A study of Mus musculus with 15 samples.

How the data were processed

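Messenger RNA levels were compared in 15 mouse libraries. Of these, 4 came from J1 cells, a line of mouse embryonic stem cells (ESCs) grown without feeder cells: 2 control libraries and 2 libraries labelled as overexpressing Zscan4. The other 11 came from 2-cell embryos, 5 control and 6 labelled as Zscan4 RNAi. Groups were taken from the genotype and title labels. The labels give genomic DNA as the library source, name a transposase-based DNA library kit and repeat the stem cell growth protocol for the embryos, while every title says RNA-Seq; the values themselves are gene-level and were treated as RNA-Seq. Nothing in the labels says that the replicates came from separate cultures or separate pools of embryos, so the p-values measure only the spread between these samples, which may be technical.

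Reads were handled with Trimmomatic, HISAT2 and featureCounts against mm10, per the submitters' processing notes. Versions, the gene annotation, strand settings, the treatment of reads that match several genes and the normalisation step are not given in the sources used here. The authors deposited 1 table for the ESCs and 1 for the embryos, and the unit of both is a normalised signal: gene read counts divided by 1 size factor per library. This was read from the values, because 100% of them in each library are whole multiples, within 0.01 of 1 read, of a fixed step. Dividing by that step gave back whole reads. The factors recomputed from those reads by the median-of-ratios method differed from the authors' by at most 0.08% in the ESC table and by 0% in the embryo table. The tables were normalised separately, so levels are compared only within a table.

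The ESC table holds 51627 genes, of which 51348 identifiers were found in GENCODE vM21 (GRCm38, the same assembly as mm10), and 98 symbols stand for more than 1 gene. The embryo table holds 53564 genes, and 53415 symbols were found in that annotation. Positions are from GENCODE vM21, in mm10 coordinates. The 5 embryo control columns are numbered from 1 to 5, whereas the labels number the controls differently, so the column numbers only name the libraries. Because the strand setting of the counting is unknown, genes that overlap another gene, on either strand, have uncertain values. Zscan4 genes are near-identical copies, and the single copies are likewise uncertain; the sum over the family was used as the main value.

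Depth was 21820093 to 26555027 reads assigned to genes per ESC library and 695524 to 1432566 per embryo library. A single read was worth 0.687 to 1.39 normalised reads in the embryo libraries, so low genes there move in coarse steps. Intervals and floors given for low counts cover counting error only, since the reads carry no molecular identifiers. A gene with no read in a group was given a floor of 3 reads over the whole group, and a ratio with 1 to 3 reads on the lower side was computed from the summed reads with its 95% exact binomial interval.

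The test designs, the alternatives, the gene lists and the rule for named genes were fixed before the data were examined. The design foresaw raw counts or normalised units such as FPKM; as the unit proved to be counts divided by size factors, the test foreseen for normalised values was used. It was limma (version 3.58.1) with a trend on log2(value + 1), on genes with a value of at least 1 in at least 2 ESC libraries or at least 5 embryo libraries, with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. Fold changes are on the log2(value + 1) scale, which understates the change of low genes; ratios of group means are called fold. Each comparison was fitted on its own libraries without covariates. On simulated data with 200 changed genes, the ESC fit over 21041 genes recovered 1.5% of 2-fold, 43.3% of 4-fold and 80.3% of 8-fold changes, and 7 of its 90 calls were false. The embryo fit over 16514 genes recovered 3% of 2-fold, 64.2% of 4-fold and 83.3% of 8-fold changes, and 10 of its 110 calls were false. The simulation gave both groups the same spread and changed only genes with a mean value of at least 10. In the real ESC libraries the median SD on the log2 scale was 0.09 for controls and 0.41 with overexpression. The simulated ESC rates therefore do not carry over to the real ESC calls.

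Before averaging, replicates were compared by a chi-square test of their reads. The chi-square per degree of freedom was 2.74 between the ESC controls and 140 between the overexpression libraries, 8.07 to 25.7 between pairs of embryo controls and 11.3 to 30.7 between RNAi pairs. All pairs differed by more than sampling noise, and each library was counted as 1 replicate.

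There were 27 gene lists with 764 genes, written from general knowledge of early embryos and ESCs; 7 genes stand in more than 1 list. Lists with at least 5 measured members were tested with camera in limma at a preset correlation of 0.01, again with an estimated correlation and with fry, each with Benjamini-Hochberg adjustment over the lists. The list of co-repressor complexes and that of proteasome and ubiquitin ligases follow the title of the series, which speaks of Zscan4, ubiquitination and co-repressors. The 2 comparisons were set against each other by one-sided Fisher's exact tests of shared calls and by camera. The sum of the Zscan4 genes was compared by a two-sided exact permutation test.

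Named genes followed a rule. They are every Zscan4 gene; the 6 largest increases and 6 largest decreases among genes past the threshold, with a group mean of at least 2 and no overlap between groups, leaving out predicted genes outside the lists; the 2 members of each list with the smallest p; and, for the overlap, the 5 genes with the smallest larger p. Genes named because they go against their list's direction, and the members of small counts, were chosen after their values were seen.

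The alternatives were other scalings (median-of-ratios, upper quartile, quantile, TMM, and factors computed without Zscan4 or without mitochondrial and ribosomal RNA genes), a pseudocount of 0.1, no filter, a stricter filter, a 2-fold threshold, each library left out in turn, a replicate block for the ESCs, DESeq2 (1.42.0), voom with quality weights and edgeR (4.0.16) on the recovered reads. TMM, edgeR, the spread taken from the overexpression libraries alone, leaving out 2 embryo libraries together, leaving out 3 chromosomes and stratifying the overlap by expression were added after the data were seen. On the recovered reads, edgeR's quasi-likelihood test called 5002 genes in the ESCs and 2417 in the embryos. Analyses ran in R 4.3.3 and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. Chromatin accessibility and protein levels are not analysed here.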

Results

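Gene expression was measured by RNA-Seq in J1 mouse ESCs with and without Zscan4 overexpression (2 libraries each) and in 2-cell mouse embryos with and without Zscan4 RNAi (6 and 5 libraries). Zscan4 is a family of SCAN-domain zinc finger genes transcribed in 2-cell embryos and in a small fraction of ESCs. The ESC libraries held 21820093 to 26555027 reads assigned to genes and the embryo libraries 695524 to 1432566. Values are reads divided by the authors' size factors, called normalised reads. Group values are mean ± SD over 2 control and 2 overexpression ESC libraries, or over 5 control and 6 RNAi embryo libraries.

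The first comparison asks which genes change when ESCs carry more Zscan4. The Zscan4 genes, in a cluster on chromosome 7 between positions 10794242 and 11614112 (mm10), were 108.4-fold higher in the overexpression libraries. Their sum was 182 ± 41.8 normalised reads in the controls (152 and 212) and 19727 ± 393 with overexpression (20005 and 19449), a log2 ratio of 6.76. The exact permutation p was 0.333, the smallest that 2 libraries against 2 can give. All 9 measured Zscan4 genes rose at an adjusted p under the threshold in limma. Zscan4c rose from 37.2 ± 8.23 to 10453 ± 763 normalised reads (log2 fold change 8.11, SE 0.23, adjusted p = 0.0112), and Zscan4f from 33.4 ± 13.6 to 4469 ± 695. The copies share 48.4% to 90.1% of their 50-base sequences with another copy, so the split between them is uncertain.

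**Figure D1:**
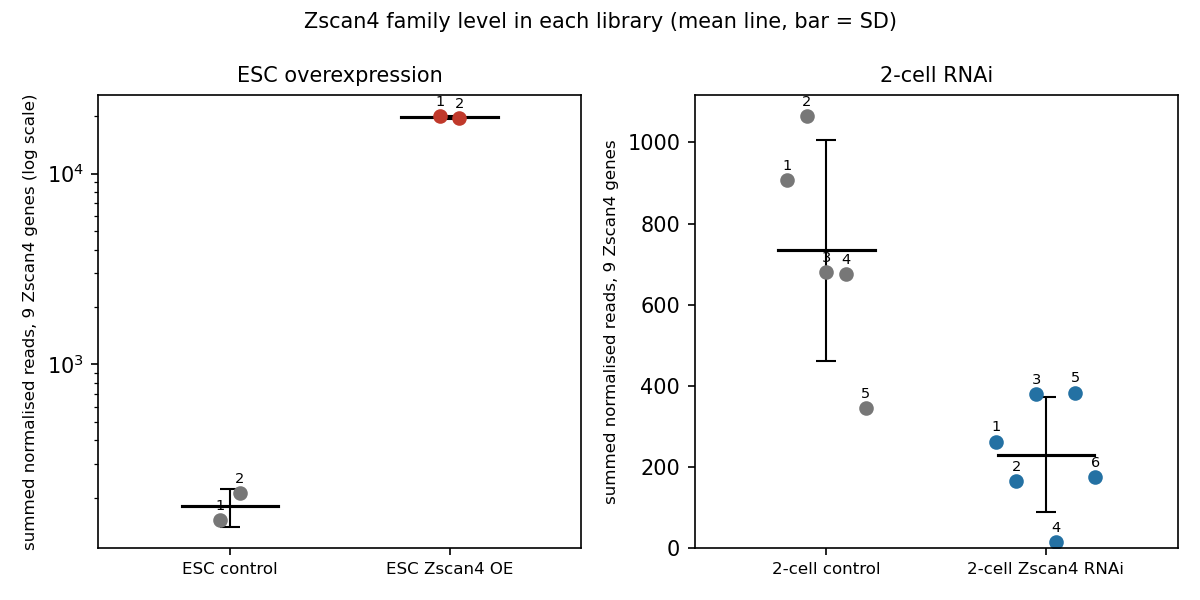
Summed normalised reads of the 9 Zscan4 genes in each library (points, numbered by replicate) with group mean (line) and SD (bar); the ESC axis is logarithmic, the embryo axis linear. The overexpression libraries stood at 20005 and 19449 against 152 and 212 in their controls, and the RNAi libraries at 13.9 to 383 against 345 to 1064.

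Overexpressing ESCs differed from control ESCs in genes of several embryonic programmes. Genes of the PRAME family, known from preimplantation embryos, were among those with the largest increases. Pramel7 (chromosome 2, positions 87489087 to 87497093) stood at 905 ± 75.7 normalised reads against 0.468 ± 0.66 in the controls. The controls held 1 read of Pramel7 together, and the ratio of the summed reads was 1900 with a 95% interval of 341 to 75200. Pramef17 reached 566 ± 24.2, with 3 reads in the controls and a ratio of 398 (136 to 1930). Pramel6 was not detected in the controls and reached 179 ± 54.2, at least 126-fold higher. Drd3, a dopamine receptor gene, rose 178.5-fold to 1770 ± 846. Gm6763, a predicted gene held in the 2C list that overlaps Gm21293, rose 114.2-fold to 544 ± 71.9.

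The largest decreases were in genes of other kinds. Chrnb4 (chromosome 9, positions 55028154 to 55048779), a nicotinic acetylcholine receptor subunit, fell from 153 ± 6.53 normalised reads to no read, at least 96.7-fold lower. Bhlhe41, a transcriptional repressor, fell from 726 ± 21.9 to 7.26 ± 5.21. The metallothionein gene Mt3 fell from 200.4 ± 33.2 to 3 reads in the group, a ratio of 129 (43.9 to 629), and the glutathione peroxidase gene Gpx6 from 142 ± 7.62 to 3 reads, a ratio of 91.4 (31 to 446). The carbonic anhydrase gene Car12 fell 55-fold. Rgs9, a regulator of G protein signalling, fell 70.9-fold; it lies on chromosome 11, whose 1537 tested genes had a median log2 fold change of -0.49. Chrnb4 overlaps Gm47877, and its value is uncertain for that reason.

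Over all 20888 genes tested, 4843 (23.2%) passed the threshold, 2453 higher and 2390 lower, so 50.7% were higher. That share was 61.3% in voom with quality weights on the recovered reads, with 2310 higher and 1457 lower of 16335 genes tested. The libraries of the groups did not overlap for 14367 genes (68.8%), where chance gives 33.33%. The call count depends on the ESC controls: with control 1 or control 2 left out, limma called 0 genes, with 3780 and 3814 at an unadjusted p under 0.05, and it called 10552 without overexpression replicate 1 and 8512 without replicate 2. With the spread taken from the overexpression libraries alone it called 0 genes (7722 at an unadjusted p under 0.05), so the calls named here rest on the closeness of the 2 controls. Calls of Zscan4a, Zscan4b, Gm6763 and Col1a2 also ended with either overexpression replicate left out, that of Otx2 without replicate 1 (adjusted p = 0.0546) and that of Terc with DESeq2 (0.0722).

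Genes of the 2-cell stage and of 2C-like cells, the ESC state that resembles 2-cell embryos, rose as a group. Of 43 measured members other than Zscan4, 28 were higher and 1, Ddit4l (log2 fold change -1.56), was lower; adjusted over the list alone the counts were 34 and 2. The median log2 fold change was 3.51, or 3.34 with the 6 members that had no control read set to their bounds (camera adjusted p = 2.4e-11; 0.294 is the adjusted p with an estimated correlation). Besides Pramel7, Gm4340 had the smallest p in this list and rose 52.8-fold to 1695 ± 535. For the Zscan4 list itself the camera adjusted p was 2.87e-08, and the adjusted p was 0.294 with an estimated correlation.

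Ribosome biogenesis genes rose, with 20 of 55 higher and 0 lower (25 and 0 adjusted over the list alone; median log2 fold change 0.77). Utp3, a processome factor, rose from 926 ± 34.0 to 3362 ± 4.39 and Polr1b, an RNA polymerase I subunit, from 1450 ± 21.7 to 4136 ± 412. The camera adjusted p was 1.83e-07, and with an estimated correlation the adjusted p was 0.294. Pluripotency genes were higher for 12 of 34 members, with Prdm14 lower (log2 fold change -0.97) and a median of 0.67. Dppa2 rose 11.3-fold to 3419 ± 83.0 and Nr0b1 4.55-fold to 2336 ± 51.2. Adjusted over the list alone 13 pluripotency genes were higher and 2 lower, and the camera adjusted p was 0.00142 (adjusted p = 0.294 with an estimated correlation).

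Markers of trophectoderm, the outer layer of the blastocyst, rose for 11 of 18 members and fell for 0 (12 and 1 adjusted over the list alone; median 1.86; camera adjusted p = 0.000179). Primed epiblast genes were higher for 8 of 13 members and lower for 1, Sox3 (10 and 3 adjusted over the list alone; median 1.61; camera adjusted p = 0.00651, in a range of 0.000583 to 0.315 with 0.0521 when overexpression replicate 1 was left out). For both lists the adjusted p was 0.315 with an estimated correlation. The keratin gene Krt18, which is in both lists, rose 33.0-fold to 17063 ± 5555, its partner Krt8 29.9-fold to 19717 ± 5770, and the homeobox gene Otx2 7.50-fold to 1022 ± 228. Krt8 overlaps Gm36026 and Otx2 overlaps Otx2os1, so both values are uncertain.

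Imprinted genes had 8 members higher and 2, Grb10 and Slc38a4, lower of 24 (8 and 3 adjusted over the list alone; median 0.45). Igf2, a growth factor gene that overlaps Igf2os and Gm49394, rose 12.9-fold to 3059 ± 29.8, and Peg10, needed for placenta formation, rose 22.1-fold to 32190 ± 12694. The camera adjusted p was 0.0285 and the adjusted p 0.623 with an estimated correlation; it was 0.0627 after quantile normalisation, 0.0568 without control 2 and 0.717 without overexpression replicate 1, in a range of 0.00592 to 0.717 over all alternatives. The list of proteasome and ubiquitin ligase genes had 4 of 38 members higher, Psma2, Psmc4, Psmd6 and Psmd14, all proteasome subunits, and 1 lower, the ubiquitin-conjugating enzyme gene Ube2b (2 and 1 adjusted over the list alone; median 0.36). Psmd6 rose 2.21-fold to 3528 ± 395; Ube2b, on chromosome 11 and overlapping Gm26551, fell 3.45-fold to 1303 ± 45.6. The camera adjusted p of this list was 0.019 and the adjusted p 0.749 with an estimated correlation; the call also ended with control 1 (0.0706) or control 2 (0.0709) left out, after quantile normalisation (0.0937), with the replicate block (0.0561) and in fry (0.249), in a range of 0.000486 to 0.749.

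Targets of p53 and genes of glycolysis fell. Of 27 p53 targets 13 were lower and 2, Tigar and Epha2, higher (15 and 2 adjusted over the list alone; median -1.64; camera adjusted p = 0.000446, and 0.294 is the adjusted p with an estimated correlation). Ddit4, an inhibitor of mTORC1 signalling, fell from 10602 ± 151 to 766 ± 61.9 normalised reads (log2 fold change -3.79, SE 0.16, adjusted p = 0.0112), and Pmaip1, which encodes the apoptosis factor Noxa, fell 7.06-fold to 286 ± 40.3. Of 17 glycolysis genes 7 were lower and 0 higher, or 12 and 0 adjusted over the list alone. Their median was -0.87, with a camera adjusted p of 1.02e-05 and an adjusted p of 0.51 with an estimated correlation. Pfkp, a phosphofructokinase gene that overlaps Pitrm1, fell 3.95-fold to 3767 ± 464 and Pgk1 3.17-fold to 14607 ± 1405.

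The 17 other lists did not pass the camera test in the ESCs. Cytosolic ribosomal proteins had 0 of 77 members past the threshold (adjusted p = 0.954), and their mean level was 13.57 and 14.42 on the log2 scale in the overexpression libraries against 14.01 and 13.98 in the controls. Maternal transcripts had 6 higher and 5 lower of 37 (0.897); among them Bmp15, an oocyte growth factor gene, had no control read and rose to 29.8 ± 1.68, at least 21-fold, while Ybx2, on chromosome 11, fell 4.61-fold. Co-repressor complexes had 8 higher and 1 lower of 45 (0.0892), with Zfp809, a retroviral silencing factor, 5.49-fold higher at 1574 ± 412 and Chd3, a nucleosome remodeller gene on chromosome 11, 3.17-fold lower at 628 ± 21.8. The 15 mitochondrially encoded genes had 8 higher and 1, mt-Rnr2, lower (0.0892), and heat shock genes had 5 higher and 1 lower of 15 (0.0892). Mesoderm and neurectoderm genes had 5 higher and 2 lower of 17 (0.505) and primitive endoderm genes 5 higher and 2 lower of 22 (0.303). DNA methylation genes had 1 higher, Dnmt3b at 4.26-fold and overlapping Dnmt3bos, and 1 lower, Apobec1, of 14 (0.396). Chromatin assembly genes had 3 higher and 1 lower of 23 (0.589), meiosis genes 2 higher and 3 lower of 27 (0.134), and telomere genes 2 higher and 2 lower of 16 (0.872). Of the telomere genes Ctc1, on chromosome 11, fell 4.08-fold to 2863 ± 121 and Terc had no control read and rose to 8.42 ± 1.59, at least 5.94-fold. Interferon response genes had 3 higher and 7 lower of 24 (0.396), integrated stress and unfolded protein response genes 0 higher and 4 lower of 26 (0.726), and cell cycle genes 3 higher and 3 lower of 30 (0.897).

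Markers of other cell types were measured as well. Fibroblast or feeder genes had 3 higher and 2 lower of 15 (camera adjusted p = 0.505), with Tagln, an actin-binding protein gene overlapping Pcsk7, 18.7-fold higher at 4424 ± 1186 and Col1a2 4.86-fold higher at 258 ± 25.2. Cumulus and granulosa genes had 3 higher and 4 lower of 20 (0.726), and blood genes 0 of 6 past the threshold (0.995). Median, mean and test differed in sign for the ribosomal protein, maternal, blood and cell cycle lists, none of which passed.

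The second comparison asks which genes change in 2-cell embryos when Zscan4 is lowered by RNAi. The Zscan4 genes were 3.2-fold lower: their sum was 734 ± 272 normalised reads in 5 control libraries and 230 ± 142 in 6 RNAi libraries (log2 ratio -1.68, exact permutation p = 0.00649 over 462 assignments). The groups overlapped, since control 5 stood at 345 while RNAi 3 and RNAi 5 stood at 379 and 383; RNAi 4 stood at 13.9. All 9 Zscan4 genes had lower means with RNAi under every scaling tried, and 5 passed the threshold, Zscan4a, Zscan4d, Zscan4f, Zscan4-ps2 and Zscan4-ps3 (8 adjusted over the list alone). Zscan4f fell from 57.1 ± 24 to 14.4 ± 10.3 (log2 fold change -2.18, SE 0.58, adjusted p = 0.0153). The camera adjusted p of the list was 0.00067, and with an estimated correlation the adjusted p was 0.483. Without control 2 the adjusted p of Zscan4f was 0.0508, the highest over its alternatives (lowest 0.00288), and the call of Zscan4d was lost in 14 of 25 alternatives (0.00897 to 0.108); those of Zscan4a, Zscan4-ps2 and Zscan4-ps3 ended in 4, 2 and 1.

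Relative to other genes, RNAi embryos held less RNA of genes for ribosomal proteins, ribosome biogenesis and the 2-cell stage. They held relatively more RNA of genes whose transcripts are stored by the oocyte. The scaled values do not give the amount of RNA per embryo. Genes for cytosolic ribosomal proteins fell for 59 of 78 members and rose for 0 (68 and 0 adjusted over the list alone; median log2 fold change -2.04; camera adjusted p = 3.41e-26). Rpl6 fell from 165 ± 58.7 to 24.3 ± 17.1 normalised reads (log2 fold change -2.85, SE 0.43, adjusted p = 0.00131), and Rpl9 7.93-fold to 18.0 ± 19.7. Ribosome biogenesis genes fell for 35 of 56 members and rose for 0 (46 and 0 adjusted over the list alone; median -1.59; camera adjusted p = 1.05e-14). Nop16, a nucleolar protein gene, fell 7.18-fold to 40.4 ± 41.3 and Gnl3, the nucleostemin gene that overlaps Pbrm1, fell 4.76-fold to 21.4 ± 5.29. For both lists the adjusted p was 0.379 with an estimated correlation.

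Maternal (oocyte) transcripts rose for 27 of 68 members and fell for 1, Sohlh1 (36 and 2 adjusted over the list alone; median 1.08; camera adjusted p = 3.59e-14). E330034G19Rik rose 6.20-fold from 413 ± 57.4 to 2560 ± 1006, and Zbed3 (chromosome 13, positions 95323612 to 95337841), a maternal gene of the oocyte cortex, from 5853 ± 1953 to 25921 ± 5025 (log2 fold change 2.19, SE 0.28, adjusted p = 0.000471). Genes of the 2-cell stage and 2C-like cells fell for 25 of 49 members and rose for 1, Duxf3 (34 and 2 adjusted over the list alone; median -1.51; camera adjusted p = 1.48e-10). The homeobox gene Obox6 fell 5.16-fold to 119 ± 61.6 and B020031M17Rik 4.16-fold. For both lists the adjusted p was 0.379 with an estimated correlation.

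Control 5 lay nearest to the RNAi libraries in each of these groups. The mean log2 level of ribosomal protein genes was 5.56 in control 5, 6.70 to 7.27 in the other controls and 3.60 to 5.98 in the RNAi libraries. For maternal transcripts it was 7.68 in control 5, 7.16 to 7.37 in the other controls and 7.83 to 8.83 with RNAi. Ribosome biogenesis stood at 5.55 in control 5, 5.79 to 6.30 in the other controls and 3.35 to 5.23 with RNAi, and 2C genes at 6.07, at 6.26 to 6.94 and at 4.26 to 6.08. Control 5 also held the lowest share of mitochondrially encoded reads among all embryo libraries, 2.26%, against 2.66% to 6.05% in the others.

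**Figure D2:**
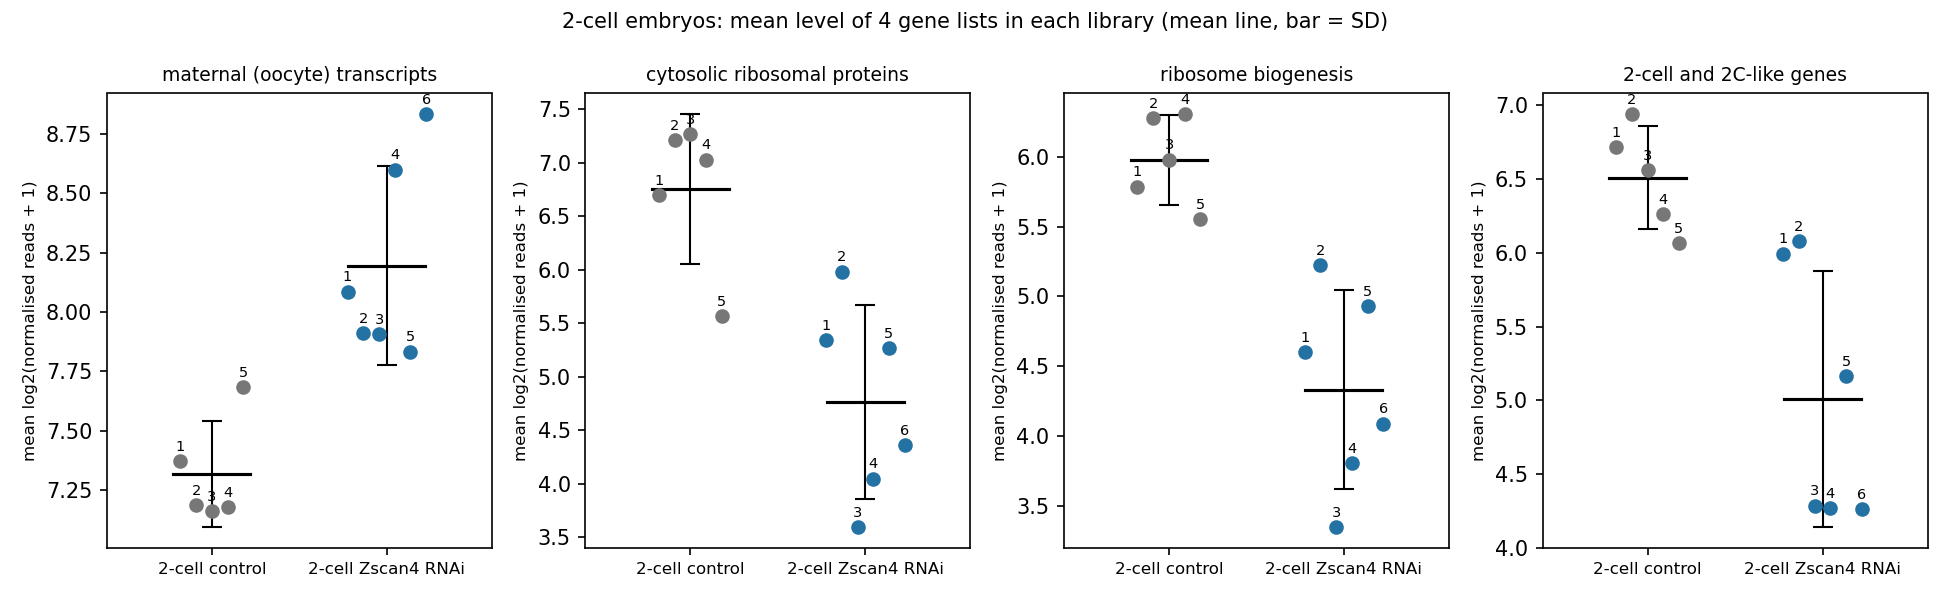
Mean log2(normalised reads + 1) of the measured members of 4 gene lists in each embryo library (points, numbered by replicate), with group mean (line) and SD (bar); the axes do not start at 0. Maternal transcripts stood at 7.32 ± 0.22 in controls and 8.20 ± 0.42 with RNAi, ribosomal protein genes at 6.75 ± 0.70 and 4.77 ± 0.91, and control 5 lay on the side of the RNAi libraries in each list.

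Cell cycle genes fell for 9 of 31 members and rose for 1, Ccnb2, a cyclin gene with a stored maternal message (14 and 1 adjusted over the list alone; median -0.98; camera adjusted p = 0.000168, and 0.543 is the adjusted p with an estimated correlation). Tyms, the thymidylate synthase gene, fell 13.6-fold to 5.22 ± 4.60 and Cdk1 4.96-fold to 96.9 ± 70.1, with control 5 at 147 for Cdk1 and the other controls at 537 to 609. Proteasome and ubiquitin ligase genes fell for 11 of 38 members and rose for 0 (11 and 0 adjusted over the list alone; median -0.48; camera adjusted p = 0.00576, and 0.598 is the adjusted p with an estimated correlation). The proteasome subunit genes Psmb5 and Psmd6 fell 13.7-fold to 3.95 ± 4.07 and 3.28-fold to 19.2 ± 8.34.

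Single genes with the largest increases were low in the controls. Duxf3, which encodes the 2C activator DUX, rose from 0.699 ± 1.10 to 27.8 ± 38.2 (log2 fold change 3.46, SE 0.73, adjusted p = 0.00502); RNAi 6 stood at 103 and the other RNAi libraries at 4.81 to 31.3. The ubiquitin-conjugating enzyme gene Ube2d1 rose 10.4-fold to 22.3 ± 5.63, Aup1, overlapping Htra2, 12.4-fold to 14.5 ± 8.33, the complement gene C1qb 11.9-fold to 11.1 ± 6.20, the interleukin receptor gene Il2ra 6.35-fold to 13.5 ± 4.26 and Fam110c 8.01-fold to 17.3 ± 3.49. On the log2(value + 1) scale, which understates the change of low genes, the largest decrease was in Exoc3l2 (chromosome 7, positions 19463331 to 19496762). It fell from 520.4 ± 227 to 33.9 ± 52.3 (log2 fold change -5.45, SE 0.89, adjusted p = 0.00189). Bcor, the gene of a BCL6 co-repressor that is in none of the lists, fell 11.8-fold from 71.0 ± 21.6 to 6.04 ± 11.2, and AA543401, overlapping Dock3, fell 15.5-fold. Sardh, overlapping Sardhos, fell from 28.1 ± 11.6 to 2 reads in the RNAi group, a ratio of 99.6 (27.1 to 829). Bex1 and Tceal7, which overlap each other on opposite strands, fell 8.2-fold and 7.32-fold; with DESeq2 their adjusted p was 0.105 and 0.127, the highest over their alternatives (lowest 0.000406 and 0.000618).

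Of 16417 genes tested in the embryos 2983 (18.2%) passed the threshold, 1007 higher and 1976 lower, so 33.8% were higher. That share was 47.6% with upper quartile scaling and 46.5% with quantile normalisation, which moved the median log2 fold change of all genes from -0.03 to 0.15 and 0.14. The groups did not overlap for 1203 genes (7.3%; 0.43% by chance). Calls numbered 1700 without control 2, 1919 without control 3 and 1751 without control 4, and 3188 without control 5 and RNAi 4 together.

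The 18 other lists tested did not pass. Pluripotency genes had 1 higher and 9 lower of 33 (camera adjusted p = 0.0639), with Dppa5a 4.93-fold lower at 128 ± 38.4 and Fbxo15, overlapping Timm21, 4.56-fold lower. Integrated stress and unfolded protein response genes had 6 lower and 0 higher of 23 (0.0503) and heat shock genes 6 lower and 0 higher of 14 (0.0612), among them Hspb1, a small heat shock protein gene, 6.32-fold lower at 95.4 ± 55.6. Co-repressor complexes had 9 lower and 2 higher of 45 (0.266); Cbx3, the gene of heterochromatin protein HP1 gamma, fell 5.01-fold to 8.92 ± 2.60 and Tbl1xr1 rose 2.99-fold to 219 ± 83.2, with control 5 at 172. Telomere genes had 2 higher and 4 lower of 15 (0.35), with Terf1 5.42-fold lower at 13.3 ± 6.26. Chromatin assembly genes had 1 higher, Asf1b at 2.56-fold, and 4 lower of 23 (0.314). Trophectoderm genes had 2 lower, Tfap2c and Tead4, of 13 (0.314), primitive endoderm genes 3 higher and 1 lower of 15 (0.49), and primed epiblast genes 1 higher, Lef1 at 4.01-fold and overlapping Gm43352, of 8 (0.879). Mesoderm and neurectoderm genes had 1 higher, Tubb3, and 1 lower, Msx1, of 7 (0.848), meiosis genes 3 higher and 3 lower of 21 (0.857), and p53 targets 2 higher and 3 lower of 21 (0.857). Interferon response genes had 1 higher, Ddx58, and 1 lower, Ifi35, of 12 (0.905), glycolysis genes 2 lower, Pgam1 and Slc16a3, of 18 (0.417), and imprinted genes 2 lower, Igf2r and Rlim, of 19 (0.857). DNA methylation genes had 1 lower, Gadd45b, of 14 (0.857), and mitochondrially encoded genes 0 of 15 past the threshold (0.384). The calls of Tubb3, Pgam1, Slc16a3, Rlim, Tead4 and Ifi35 each ended under at least 1 alternative.

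Few markers of cells that could accompany an embryo were measured. Fibroblast genes had 0 of 7 past the threshold (camera adjusted p = 0.857). Cumulus and granulosa genes, with 4 measured, and blood genes, with 3, were too few for a test, and 1 of them, Serpine2, passed the threshold, at 43.4 ± 20.8 in controls and 322 ± 431 with RNAi, where RNAi 4 stood at 1195. Median, mean and test differed in sign for the meiosis, p53, interferon and imprinted lists.

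**Figure D3:**
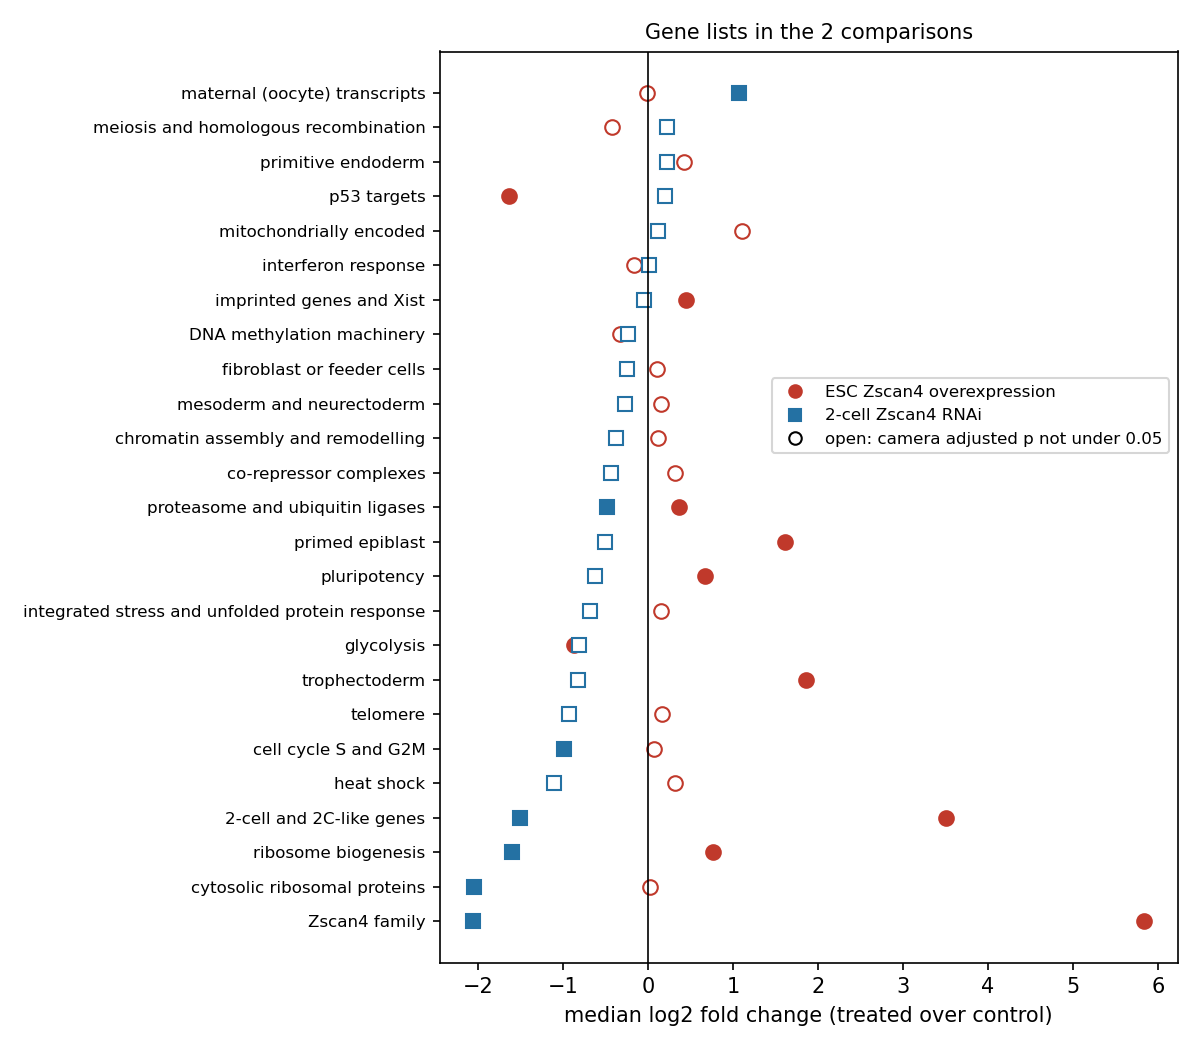
Median log2 fold change of each gene list tested in both comparisons, for ESC overexpression (circles) and 2-cell RNAi (squares); open symbols mark a camera adjusted p not under the threshold at the preset correlation. The 2C list stood at 3.51 with overexpression and -1.51 with RNAi, ribosome biogenesis at 0.77 and -1.59, and ribosomal proteins at 0.03, with a flip of sign to -0.04 under another scaling, and -2.04.

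The third comparison asks whether genes that move with more Zscan4 in ESCs move the other way with less Zscan4 in embryos. Among 13067 genes tested in both, 326 were higher with overexpression and lower with RNAi, where 215.1 are expected from independent lists (odds ratio 1.79, 95% interval 1.56 to 2.05, one-sided Fisher's exact p = 1.15e-16). These included 16 of 42 genes of the 2C list, 14 of 55 ribosome biogenesis genes, 5 Zscan4 genes, 4 pluripotency genes and 4 heat shock genes. Another 110 were lower with overexpression and higher with RNAi, against 83.7 expected (odds ratio 1.4, 1.12 to 1.73, Fisher's exact p = 0.00145). In the same direction, 83 were higher in both (99 expected) and 92 lower in both (181.8 expected). Fisher's tests treat genes as independent, which they are not, so these p-values and intervals overstate the certainty. Among 100 splits of the embryo libraries with equal numbers of lower genes, 2, the real one among them, gave an overlap of at least 326.

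The 5 genes of these opposite overlaps with the smallest larger p were Pramel6, Trim43a, Zfp936, Rpl10l and Grm4. Pramel6, the PRAME-family gene absent from control ESCs, fell 5.62-fold with RNAi, from 113 ± 34.7 to 20.1 ± 15.2. Trim43a, a 2-cell-stage gene, rose from 2.82 ± 1.30 to 399 ± 20.5 in ESCs and fell from 478 ± 221 to 97.2 ± 84.8 in embryos. The zinc finger gene Zfp936 rose 9.01-fold and fell 7.06-fold, and Rpl10l, a retrogene of a ribosomal protein, rose 14.3-fold and fell 5.91-fold. Grm4, a glutamate receptor gene, went the other way, 30.8-fold lower with overexpression and 4.96-fold higher with RNAi.

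The genes higher with overexpression were lower as a set in the RNAi comparison (camera adjusted p = 0.0208), and those lower with overexpression were higher in it (0.0353). The genes lower with RNAi were higher with overexpression (0.000516), whereas those higher with RNAi did not pass (0.332). With an estimated correlation the adjusted p was 0.256 for the first 3 sets and 0.498 for the last. Across genes, which are not independent replicates, Spearman's rho of the fold changes was -0.122. With ESC control 1 or 2 left out no ESC gene passed in limma, and both overlaps were 0; without overexpression replicate 1 the overlap of genes lower with overexpression and higher with RNAi was 217 against 223 expected (Fisher's exact p = 0.699).

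**Figure D4:**
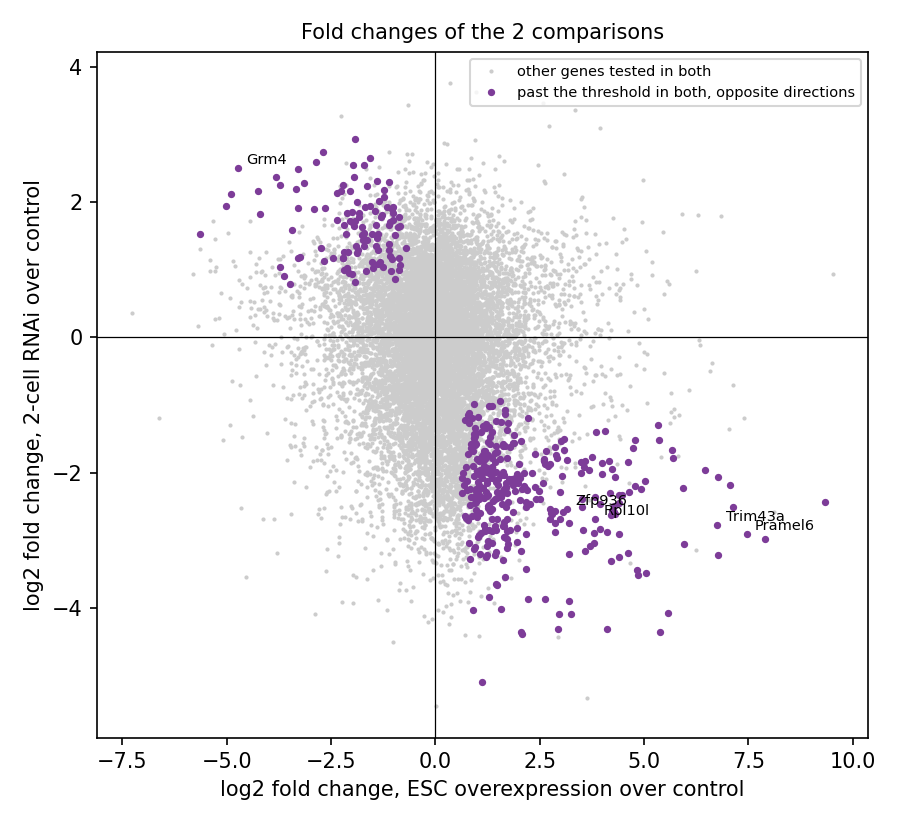
Log2 fold change of each gene tested in both comparisons, with ESC overexpression on the x axis and 2-cell RNAi on the y axis; purple points passed the threshold in both with opposite signs. The lower right holds 326 such genes and the upper left 110, and the 5 genes with the smallest larger p are named.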

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

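The test of where each control library lies along the RNAi effect, the splits with equal numbers of lower genes, the alternative with the spread taken from the overexpression libraries alone and the edgeR counts were chosen only after the result was seen. Of 210 groups of values in the embryos, 23 had a single library far from the others of its group, by the gap to its nearest neighbour as a share of the group's range (Dixon's test); chance gives about 1 in 20.

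RNAi 2 held 7 of these values. Its heat shock list had a mean log2 level of 6.16, against 5.12 to 5.40 in the other RNAi libraries. Its normalised reads were 11.48 for Ube2d1 (others 21.7 to 27.5), 136.1 for Exoc3l2 (0 to 39.1), 55.8 for Rpl9 (4.34 to 20.7), 58.2 for Pgam1 (7.55 to 26.2), 126.3 for Zfp936 (40.4 to 59.9) and 50.8 for Rpl10l (3.48 to 17.1). RNAi 5 stood high for Bcor at 28.9 (others 0 to 2.61), Dppa5a at 202 (89.4 to 123.6), Fbxo15 at 196.6 (46.4 to 100) and Tead4 at 7.21 (0 to 2.46).

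In RNAi 4 the meiosis list had a mean log2 level of 4.43 (others 4.84 to 5.08), with Thy1 at 9.29 (0 to 3.43) and Serpine2 at 1195 (98.9 to 241). RNAi 6 stood high for Duxf3 at 103.3 (4.81 to 31.3) and Tet3 at 390.5 (208.3 to 247.3), and RNAi 3 for Lef1 at 332.5 (92.7 to 150.9). Among the controls, control 5 had a mean log2 level of 8.78 for the mitochondrially encoded genes (others 9.79 to 10.14), with Smarca5 at 51.8 (156 to 185), Cdk1 at 146.6 (537 to 609) and Tbl1xr1 at 172 (29.3 to 59.8). Control 2 stood at 3.69 for C1qb (0 to 0.978) and control 4 at 43.3 for B020031M17Rik (81.3 to 93.8).

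In the RNAi embryos maternal transcripts were higher and genes of ribosomes and of the 2-cell stage lower, and control 5 lay towards the RNAi side in each of these 4 lists. Gene length with GC content, and depth, are argued against as the whole cause, since each list kept at least 93.8% of its median log2 fold change after a loess on the former and at least 94.6% with every library thinned to 695524 reads. A position along the maternal-to-zygotic transition that also varies among control embryos stays open: control 5 deviated from 2 other controls along the RNAi effect against the remaining controls with a correlation across genes of 0.403 (mean over 6 divisions), while the other controls stood at -0.184 to -0.014. This is consistent with a difference in developmental timing or embryo quality between samples, and a slower transition when Zscan4 is lowered would look the same. The time of collection is not given in the sources used here, and an effect of the RNAi itself stays open as well.

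Other splits of the 11 embryo libraries into groups of 5 and 6 were drawn, 100 of 462 with the real one among them. For the 2983 genes past the threshold chance is argued against, as 1 of the 100 drawn splits, the real one, gave as many. That is the smallest share that 100 splits can show, and the highest other count was 1042. Since 94 of the other splits called 0 genes in limma, the overlap with overexpression was counted among the 1716 lower genes of smallest p in every split. The real split gave 326, 2 of the 100 splits, the real one among them, gave as many, and the highest other count was 327. The median of the other splits was 211. Chance is argued against at that share but not excluded, since another split exceeded the real one. For the count of 7 lists chance is not argued against, since 22 of 100 splits gave as many and the highest gave 10. A camera p as small as the real one came in 1 of the 100 splits for ribosome biogenesis, in 2 for ribosomal proteins and for maternal transcripts, in 9 for the 2C list, in 21 for cell cycle, in 23 for the Zscan4 list and in 29 for the proteasome list. A median log2 fold change as large came in 1, 2, 1, 2, 1, 2 and 9 of them, in the same order of the lists.

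The control ESC libraries were far more alike than the overexpression libraries, with a median SD of 0.09 against 0.41 on the log2 scale and a chi-square per degree of freedom of 2.74 against 140. With the spread taken from the overexpression libraries alone limma kept 0% of its calls, with 7722 genes at an unadjusted p under 0.05 where chance gives 1044; this test has 1 residual degree of freedom, so the lack of calls does not show that genes did not change. With the spread from the controls alone it called 13638 genes, and on the recovered reads with both spreads edgeR called 5002, DESeq2 5261 and voom 3767. A candidate explanation is a spread that is too small because the controls are near-technical replicates. A response to overexpression that varies between cultures was not tested and stays open, and whether the controls came from separate cultures is not given in the sources used here.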

How the results depend on the processing

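TMM scaling, edgeR, the spread from the overexpression libraries alone, leaving out 2 embryo libraries together, leaving out 3 chromosomes and the stratified overlap were chosen only after the result was seen. In the ESCs limma called 4843 genes; it called 0 with the spread from the overexpression libraries alone (7722 at an unadjusted p under 0.05) and 0 to 10552 with each library left out, where the lone library of a group is assumed to vary like the other group. The 0 came without control 1 or control 2 (3780 and 3814 unadjusted; edgeR 5002 and DESeq2 5261 with all libraries), and the other alternatives gave 3429 to 6024. In the embryos the count was 2983, with 1700 to 3548 when each library was left out (1700, 1919 and 1751 without controls 2, 3 and 4; the cause was not tested) and 2272 to 3554 otherwise; voom called 3554, edgeR 2417 and DESeq2 3161. With an estimated correlation 0 of 10 ESC lists and 0 of 7 embryo lists passed in camera; the cause was not tested. Fry, run on the same values, passed 15 ESC lists, 9 of them among the 10, and 12 embryo lists, all 7 among them; the cause of the rise was not tested. Without single libraries 8 to 12 and 7 to 10 lists passed. The overlap of genes higher with overexpression and lower with RNAi was 0 to 755 and the opposite overlap 0 to 217 with each library left out; both were 0 without ESC control 1 or control 2, since limma then called no ESC gene. The 217 genes, without overexpression replicate 1, lay below the 223 expected (Fisher's exact p = 0.699; the cause was not tested). Stratified by expression, the overlaps had a two-sided Cochran-Mantel-Haenszel p of 2.09e-21 and 0.00757 (ESC deciles) and 4.56e-17 and 6.83e-07 (embryo deciles). This chi-square test is not exact, is two-sided where the Fisher's tests were one-sided, and also treats genes as independent. The sum of the Zscan4 genes kept its direction, with a log2 ratio of 6.54 to 7.02 in the ESCs and -1.43 to -1.89 in the embryos without single libraries (exact permutation p at most 0.0238 in the embryos). Of single named genes, mt-Nd5 moved from a log2 fold change of 0.467 to -0.083 under quantile normalisation, past the threshold in neither; the cause was not tested. Over all named genes and alternatives, 1224 ESC results kept direction and side of the threshold, 225 lost their call and 10 gained one; in the embryos 1823 kept both, 72 lost it, 25 gained one and 1 turned. The ESC replicate numbers showed no sign of pairing: across 20888 genes the difference between the controls and that between the overexpression libraries had a correlation of -0.007 (Spearman's rho -0.027). The controls differed little from each other (chi-square per degree of freedom 2.74), so this cannot tell whether the replicate numbers pair. With the number as a block limma called 6024 ESC genes, 4408 of them among the 4843, and 10 lists, 9 of them among the 10, and the Zscan4 log2 ratio was 6.78. No paired analysis was possible because the embryo table numbers its control columns 1 to 5 and the labels number the controls 3 to 7, so that no column can be tied to a label. With every embryo library thinned to 695524 reads limma called 2829 genes, 2650 of them among the 2983. On simulated data at these depths and replicate numbers limma recovered 1.5% of 2-fold changes in the ESCs and 3% in the embryos, and DESeq2 19.4% and 10.4%, with 42 of its 162 and 23 of its 142 calls false. These rates assume the same spread in both groups, which the real ESC libraries did not have.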

Other observations

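The search over gene families, the tests of 4 equal parts of chromosome 11, of its median and of the share of its genes that moved, and the list tests without chromosomes 11, X and Y were chosen only after the result was seen. Families were taken from the shared start of gene names, with at least 10 tested members, and 16 of 666 one-sided Fisher's exact tests passed the threshold; members of a family are not independent. The Rpl and Utp families with RNAi and the Zscan family with overexpression passed too and overlap lists described above. Each family named here kept the sign of its median under every scaling tried. In the RNAi embryos the lower genes included more of several families than expected, counted with members that also stand in the ribosome lists, such as Polr1b: 14 of 36 Ddx RNA helicase genes (4.3 expected; median log2 fold change -1.13, adjusted p = 0.00403; below every control in 6 of 6 libraries), 12 of 28 Polr RNA polymerase subunit genes (3.4 expected; -1.17, 0.00403; 6 of 6), 20 of 57 Eif translation initiation genes (6.9 expected; -0.86, 0.00109; 5 of 6) and 6 of 10 Srsf splicing factor genes (1.2 expected; -1.60, 0.0274; 5 of 6). Obox homeobox genes, which are transcribed in eggs and early embryos, were lower for 10 of 21 (2.5 expected; -1.55, 0.0052; 5 of 6).

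In the overexpressing ESCs 75 of 395 Zfp zinc finger genes were higher (46.4 expected; median 0.31, adjusted p = 0.00222), as were 12 of the 36 Ddx genes (4.2 expected; 0.35, 0.0316), 10 of 27 Platr transcripts, noncoding RNAs named for their link to pluripotency (3.2 expected; 0.90, 0.0316), 7 of 15 Serpinb protease inhibitor genes (1.8 expected; 1.86, 0.0347) and 6 of 11 Akr aldo-keto reductase genes (1.3 expected; 1.78, 0.0316). Solute carrier genes (Slc) were lower for 59 of 321 (36.7 expected; -0.17, 0.0115), regulators of G protein signalling (Rgs) for 8 of 19 (2.2 expected; -1.49, 0.0316) and sodium channel genes (Scn) for 6 of 11 (1.3 expected; -1.48, 0.0316). Both overexpression libraries lay beyond both controls in the mean level of each of these families. These ESC calls share the dependence on the 2 controls given for all ESC genes.

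Genes of chromosome 11 were lower as a whole in the overexpressing ESCs: the median log2 fold change of its 1537 tested genes lay at -0.51 from that of all other genes, with medians of -0.58 and -0.47 in the 2 overexpression libraries against the control mean and 0 between the controls, and 353 of the 2390 lower calls (14.8%) were on this chromosome, which holds 7.4% of the tested genes. The difference was 0.32 for chromosome X and 0.756 for Y, where 24 genes were tested. A candidate explanation is a difference in the number of chromosome 11 copies between the cultures, in all or some of the cells, since 2 copies against 3 give a log2 ratio of -0.585; a change in part of the chromosome is argued against, as 4 parts with equal numbers of genes along it stood at -0.591 to -0.408 from all other genes. A few strongly changed genes are argued against as well, since they would leave the median near that of all other genes, and the 95% bootstrap interval of the difference was -0.581 to -0.43; the share of its genes below the median of all others, 67.9%, lay between bounds of 60 and 70 set first, which did not allow for the spread of single genes. Without the genes of chromosomes 11, X and Y limma called 4120 genes and all 10 lists passed. This argues against the genes on these chromosomes as the source of the list results. It cannot tell whether a change of these chromosomes, or another difference between the cultures, altered genes elsewhere. DNA copy number was not analysed here, and no biological explanation was tested.

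Reads of an overexpressed Zscan4c could be counted on its near-identical copies and so raise all Zscan4 genes together. Across the other 8 genes the share of 50-base sequences found in Zscan4c and the log2 fold change had a Spearman's rho of 0.071. With 8 genes this lies between the bounds set for the test, and shared reads and a rise of the other copies cannot be told apart.

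A graded effect of Zscan4 would let RNAi libraries with less Zscan4 hold more maternal RNA. Across the 6 RNAi libraries the sum of the Zscan4 genes and the maternal score had a Spearman's rho of -0.714 (exact p = 0.136, 0.544 adjusted over 4 relations) and a Pearson correlation of -0.693 (exact permutation p = 0.149, 0.596 adjusted), which was -0.475 without RNAi 4 and RNAi 5. The relation did not pass, and with 6 libraries its presence and absence cannot be told apart. For the other 3 lists Spearman's rho was -0.086 for ribosomal proteins, 0.029 for ribosome biogenesis and 0.143 for 2C genes (exact p = 0.919, 1 and 0.803). Their Pearson correlations of 0.026, 0.042 and 0.127 moved to -0.689, -0.768 and -0.374 without RNAi 4 and RNAi 5, so they rest on those 2 libraries.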
